A study of Mus musculus with 18 samples.

How the data were processed

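The series measured total liver RNA from 18 male C57Bl/6 mice, an inbred laboratory strain, with 1 Affymetrix GeneChip expression array per mouse. Per the labels' protocols, all animals ate a low-fat diet for 3 weeks and were then kept on it or moved to a high-fat diet, in which palm oil took the place of lard, for 21 weeks. The submitters sorted the animals afterwards by how the same livers looked under the microscope. This gave 4 groups: low-fat low responders with normal liver (LFL, 4 arrays), low-fat high responders with benign steatosis (LFH, 6 arrays), high-fat low responders with early disease and large lipid droplets (HFL, 4 arrays), and high-fat high responders with overt nonalcoholic steatohepatitis (HFH, 4 arrays). The phenotype labels call the same classes low and high gainers, while the protocol text speaks of responders judged on histology, and the groups here follow the codes in the sample titles. Since animals were not assigned at random to the responder classes, the comparisons between classes are between animals sorted by outcome. The same holds for comparisons between diets within a class, since the class was set after the diet.

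The deposited values were log2 expression per probe set, already normalized by the authors with GCRMA 2.2.0, per the submitters' processing notes. GCRMA subtracts a background estimated from probe sequence, so genes with little or no signal collect near a low value and fold changes against that value depend on the background model. The scan order and scanner batch were not given in the sources used here. The table held 45101 probe sets, of which 64 were control probe sets that were left out. In the platform annotation 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Only probe sets with 1 symbol were named, covering 18193 genes, and 0 symbols needed updating through their gene identifiers. No genome build is named for these values, so no coordinates are given.

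The tests started from the deposited values without further normalization. A probe set was kept when it lay above the log2 of 20 (4.32) on at least 4 of the 18 arrays, in whichever groups those arrays were. The design written beforehand said 4 arrays of any group, which can also be read as 4 arrays of the same group, and that reading was run as an added alternative. Of the probe sets, 13428 passed, and the probe set with the highest mean over all arrays stood for each gene, which left 7634 genes. For 2945 of them several probe sets passed. For 972 the probe set ended in _x_at or _s_at, a mark that its probes can also bind related transcripts, and values of such genes are uncertain where a close paralog exists (among those named below Gstm3, Srxn1, Krt8, Ifi27l2b, Socs3, Vldlr, Slc22a27, Slc13a3, Acta2, Hamp2, Hsd17b7, Tkt and Serpina4-ps1). Where every array of the dimmer group lay below the log2 of 20, the fold is given as a bound against that value. A fitted log2 fold change or interaction printed for such a gene depends on the background model. So does the size of a fold where the mean of the dimmer group lay below the log2 of 20 but single arrays lay above it.

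Groups were compared with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 18 arrays, contrasts were tested with eBayes (trend in the prior variance), and p-values were adjusted over all 7634 genes with the Benjamini-Hochberg method. A gene was called changed at an adjusted p under 0.05, and all tests were two-sided. The 6 contrasts were HFH against HFL, LFH against LFL, HFL against LFL, HFH against LFH, HFH against LFL, and the interaction, which is the first of these minus the second. Precision is limited by the number of arrays.

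Before the data were examined, 37 gene lists were written down for pathways, cell types and other tissues relevant to fatty liver. Of their 906 entries 808 were on the array, and 30 lists had at least 5 tested members. The lists for T and NK cells (0 members tested), B and plasma cells (3), neutrophils (1), cholangiocytes (2), pancreas (1), blood cells (3) and muscle (0) had too few. Lists were tested with camera in limma at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists of a contrast, and again with the correlation estimated from the data. Beside each camera result stand the members that passed the gene test, adjusted over all genes, and those that passed when adjusted over the list alone. fry in limma, which asks whether the genes of a list move on balance in a single direction and does not compare them with other genes, was an alternative. Some genes belong to more than 1 list. Examples are Slco1a1 and Cyp7b1 (male-biased and bile acid), Mmp12 (matrix and macrophage) and Cidec (lipid droplet and adipocyte).

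The genes named in the text follow a rule also fixed beforehand. For HFH against HFL, LFH against LFL and HFL against LFL these were the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between groups, and for the other contrasts the 5 largest each way (for the interaction without the condition on overlap). Up to 4 called members of each called list were added, in the direction of the list and by smallest p. Where fewer than 5 genes passed, the 5 with the smallest p are given as not passing. A panel of genes tied to the histology may be given in any case, of which Col1a1, Timp1, Ccl2 and Tnf lay below the expression filter and were not tested. A gene named outside this rule is said to be so where it appears.

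The gene test was checked on simulated data for HFH against HFL with the 7634 genes. Of 50 genes changed by 0.5 on the log2 scale 32 were called, of 50 changed by 1 there were 41, of 50 changed by 2 there were 49, and of 50 changed by 4 all 50. Of 7434 unchanged genes 11 were called. The simulated noise was normal, independent between genes and of the same SD in all groups. These figures hold for that setting and not for correlated genes or groups of unequal spread.

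The alternatives were no expression filter, a stricter filter (mean above the log2 of 100), all probe sets, the median of a gene's probe sets, arrays centred on their median, quantile normalization, eBayes without trend, array quality weights, a fit of the compared groups alone (robust eBayes for the interaction), the replicate number as a block, each array left out in turn, probe sets ending in _x_at or _s_at left out, and a limit of 2-fold. After the data were seen, 3 more were added: leaving out both arrays that stood apart (LFL replicate 1 and LFH replicate 2), a score of circadian clock genes as a covariate, and the other reading of the filter. For the score each gene was standardised over the arrays, the sign of Arntl, Clock, Npas2, Cry1 and Nfil3 was turned, and the mean was taken with Dbp, Tef, Hlf, Per3, Nr1d1, Nr1d2, Usp2, Bhlhe41 and Wee1. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.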

Results

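Liver expression profiles were compared between 18 mice in 4 histological groups, LFL (normal liver on the low-fat diet, n = 4), LFH (benign steatosis on the low-fat diet, n = 6), HFL (pre-NASH on the high-fat diet, n = 4) and HFH (overt NASH on the high-fat diet, n = 4). Each array carried 1 mouse, so the spread between arrays includes the spread between animals. Array medians lay between 2.341 and 2.382 on the log2 scale, and the correlation between arrays over genes ranged from 0.9551 to 0.992. The first principal component held 36.6% of the variance. Markers of adipose tissue stood out on LFH replicate 2 alone, where Adipoq read 8.9 against at most 2.66 on any other array. LFL replicate 1 read 7.74 for the lipid droplet gene Cidec, while the other LFL arrays read at most 3.25. A score of circadian clock output genes averaged -0.72 ± 0.85 (SD, n = 4) in LFL, 0.14 ± 1.03 (n = 6) in LFH, -0.12 ± 0.57 (n = 4) in HFL and 0.62 ± 0.14 (n = 4) in HFH.

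Overt NASH was compared with pre-NASH on the same high-fat diet. Of 24 genes listed beforehand as higher in male than in female mouse liver, 11 fell. Rises were seen for 4 of 21 extracellular matrix, 6 of 10 hepatocyte injury and 5 of 22 NRF2 and glutathione genes. The calls of these 4 lists did not hold with an estimated correlation (adjusted p = 0.104, 0.104, 0.104 and 0.107). Hsd3b5, a steroid-metabolising enzyme of male mouse liver, went from 10.78 ± 0.56 (SD, n = 4) in HFL to 3.3 ± 1.76 (n = 4) in HFH, a log2 fold change of -7.47 (SE 0.75, adjusted p = 8.3e-05). Ly6d, a lipid-anchored surface protein that also stood in the B and plasma cell list, was at least 7.31-fold higher in HFH (adjusted p = 0.00181), and Gstm3, a glutathione S-transferase, rose by 2.24 (SE 0.36, adjusted p = 0.00465). Col3a1 and Col1a2, which encode fibrillar collagens, rose by 1.43 (SE 0.36, adjusted p = 0.046) and 1.54 (SE 0.37, adjusted p = 0.0387). This comparison asked what separates animals that developed overt disease from those that did not on the same diet. For the genes named by the rule as changed here, all 4 HFH arrays lay on the same side of all 4 HFL arrays. For the largest rises and falls the rule itself required this, so it adds no support for them.

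Of the 24 tested male-biased genes 11 fell and 0 rose in HFH against HFL, or 14 and 1 adjusted over the list alone. The median log2 fold change was -0.56 (camera adjusted p = 3.22e-12, adjusted p = 0.104 with an estimated correlation). Beside Hsd3b5 they included Slco1a1, an organic anion transporter (-2.35, adjusted p = 0.0046), Egfr, the receptor for epidermal growth factor (-1.86, adjusted p = 0.00465), and C8b, a chain of complement component C8 (-1.56, adjusted p = 0.00234). Of 13 female-biased genes 1 rose, Rtn4 (0.55, adjusted p = 0.0437), and 1 fell, with 7 up and 2 down adjusted over the list alone. The median was 0.93 (adjusted p = 0.00141, and adjusted p = 0.167 with an estimated correlation), and 0.45 with the clock score as a covariate. The fall was that of Lifr, the receptor for leukaemia inhibitory factor (-1.31, adjusted p = 0.00465), named after its values were seen. Rtn4 lost its call in 7 of 8 cases with 1 array left out, and its 2 other probe sets did not pass. Among 23 cytochrome P450 and drug metabolism genes 6 fell and 0 rose, with 10 down and 4 up adjusted over the list alone. The median was -0.15 (adjusted p = 0.00185, and adjusted p = 0.144 with an estimated correlation). Cyp2c54 fell by 1.94 (adjusted p = 0.00134) and Cyp4f14 by 1.06 (adjusted p = 0.0046). Of 25 bile acid genes 3 fell, namely Slco1a1, the sterol transporter gene Abcg5 (-0.49, adjusted p = 0.0497) and Cyp7b1, an oxysterol hydroxylase (-0.98, adjusted p = 0.00496). Slco1a1 and Cyp7b1 also stood in the male-biased list, and Abcg5 lost its call in 7 of 8 cases with 1 array left out. Adjusted over the bile acid list alone 8 were down and 1 up. The median was -0.14 (adjusted p = 0.000465, and adjusted p = 0.127 with an estimated correlation). In the hepatocyte secretory list 2 of 20 genes fell, the liver transcription factor Foxa3 (-1.03, adjusted p = 0.014) and the urea cycle enzyme Cps1 (-0.36, adjusted p = 0.0459), neither of them a secreted protein, with 6 down adjusted over the list alone. The median was -0.04 (adjusted p = 0.00185, and adjusted p = 0.104 with an estimated correlation).

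Extracellular matrix genes rose in HFH for 4 of 21 members, Mmp12, Col1a2, Col3a1 and Nid1, and for 17 with 1 down adjusted over the list alone. The median was 0.54 (camera adjusted p = 1.59e-10, adjusted p = 0.104 with an estimated correlation). Mmp12, the macrophage elastase, was also the 1 of 26 macrophage genes that rose (at least 1.99-fold, adjusted p = 0.0166), with 12 up adjusted over the list alone. The median was 0.51 (adjusted p = 6.88e-11, and adjusted p = 0.127 with an estimated correlation). The pan-macrophage markers Adgre1 (0.2, adjusted p = 0.65) and Cd68 (0.53, adjusted p = 0.328) did not pass, nor did Acta2, the smooth muscle actin of activated stellate cells (0.67, adjusted p = 0.36). In the stellate cell list 1 of 15 genes rose and 1 fell, and the list was not called (median 0.26, camera adjusted p = 0.0859). In the list for Mallory bodies and hepatocyte injury 6 of 10 genes rose and 8 adjusted over the list alone. The median was 0.61 (adjusted p = 3.59e-07, and adjusted p = 0.104 with an estimated correlation). The 6 that rose were the keratins Krt8 (0.64, adjusted p = 0.0292) and Krt18 (0.4, adjusted p = 0.0431), which form Mallory bodies, together with Ly6d, the annexins Anxa2 (1.48, adjusted p = 0.0397) and Anxa5 (1.02, adjusted p = 0.019), and the cell cycle inhibitor Cdkn1a (at least 1.66-fold, adjusted p = 0.0222). Sqstm1, another Mallory body component, was at 0.17 (adjusted p = 0.209), a value given after it was seen. Of 22 NRF2 and glutathione genes 5 rose and 7 adjusted over the list alone (median 0.37, adjusted p = 3.93e-07, and adjusted p = 0.107 with an estimated correlation), among them Gstm2 (1.14, adjusted p = 0.00828) and Srxn1, which encodes sulfiredoxin (1.04, adjusted p = 0.00465). Sprr1a, a small proline-rich protein of squamous epithelia, was at least 2.26-fold higher (adjusted p = 0.00181), and the acute phase gene Orm2 rose by 2.37 (adjusted p = 0.0137).

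Lipid droplet genes rose in HFH for 3 of 22 members, Mogat1, a monoacylglycerol acyltransferase (at least 4.13-fold, adjusted p = 0.0415), Plin3 (0.71, adjusted p = 0.0415) and Hsd17b13 (0.45, adjusted p = 0.0447), and for 6 adjusted over the list alone. The median was 0.41 (adjusted p = 3.08e-05, and adjusted p = 0.249 with an estimated correlation). Cidec, which promotes droplet fusion, was 5.13 ± 1.69 (SD, n = 4) in HFL and 8.27 ± 0.23 (n = 4) in HFH, a difference of 3.14 that did not pass (adjusted p = 0.128), as was the case for the fatty acid transporter Cd36 (1.04, adjusted p = 0.142), Plin2 (0.25, adjusted p = 0.228) and Pparg (0.66, adjusted p = 0.376). Cholesterol synthesis was called with 0 of 21 members passing over all genes or adjusted over the list alone. The median was 0.4 (adjusted p = 1.55e-05, and adjusted p = 0.289 with an estimated correlation). De novo lipogenesis was called with 0 of 23 members passing either way. The median was 0.38 (adjusted p = 0.0019, and adjusted p = 0.474 with an estimated correlation). For immediate early genes 3 of 11 rose, Klf6, Btg2 and Jun, and the same number adjusted over the list alone. The median was 0.59 (adjusted p = 0.000465, and adjusted p = 0.104 with an estimated correlation). Smaller called lists followed. For cytokines and chemokines 1 of 14 rose, the adhesion molecule gene Vcam1, and 5 adjusted over the list alone. Their median was 0.5 (adjusted p = 0.00132 and adjusted p = 0.167 with an estimated correlation). Vcam1 lost its call in 7 of 8 cases with 1 array left out, and its 1 other probe set did not pass. For interferon response 1 of 24 rose, Rsad2, and 1 adjusted over the list alone. The median was 0.16 (adjusted p = 0.0381 and adjusted p = 0.568 with an estimated correlation). Rsad2 lost its call in 4 of 8 cases with 1 array left out, and its 2 other probe sets did not pass. For cell cycle 0 of 5 rose and 3 adjusted over the list alone, with a median of 0.69 (adjusted p = 0.00132 and adjusted p = 0.133 with an estimated correlation). For MHC class II 0 of 5 rose, with a median of 0.45 (adjusted p = 0.0106 and adjusted p = 0.333 with an estimated correlation). For sinusoidal endothelium 0 of 18 rose, with a median of 0.12 (adjusted p = 0.0105 and adjusted p = 0.133 with an estimated correlation). For MHC class II and sinusoidal endothelium 0 members passed adjusted over the list alone.

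In total 192 genes differed between HFH and HFL, 80 higher and 112 lower (90 and 91 with centred arrays, 313 and 233 with only the 2 groups in the fit). Of the 192 genes 44 changed by more than 2-fold, and 18 of 30 lists were called, 14 up and 4 down, none of them with an estimated correlation. The remaining falls of the largest group were Serpina4-ps1, a serpin pseudogene on an ambiguous probe set (-5.24), the organic anion transporter Slc22a7 (-2.04), Adh6-ps1 (at least 1.31-fold), the transcriptional repressor Bach2 (-1.73) and the glucuronosyltransferase Ugt2b38 (at least 2.31-fold), and the remaining rises were Ifi27l2b (2.16) and Klf6 (at least 1.96-fold). The gene count was 31 without HFL replicate 2, 33 without HFL replicate 3, 37 without HFH replicate 1, 61 without HFH replicate 3, 63 without HFH replicate 2, 90 without either HFL replicate 1 or HFH replicate 4, and 48 with the clock score as a covariate. Of the 43 named genes called, 15 were called whichever array was left out. Among them were Hsd3b5, Slco1a1, Egfr, C8b, Cyp2c54, Ly6d, Sprr1a, Gstm3, Klf6 and Srxn1. Hsd17b13 and Bach2 lost the call in 8 of 8 cases, and Col3a1, Mogat1, Krt18, Anxa2 and Abcg5 were among those that lost it in 7 of 8. Other probe sets did not pass for Bach2 (1 of 1) and Srxn1 (1 of 2).

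**Figure D1:**
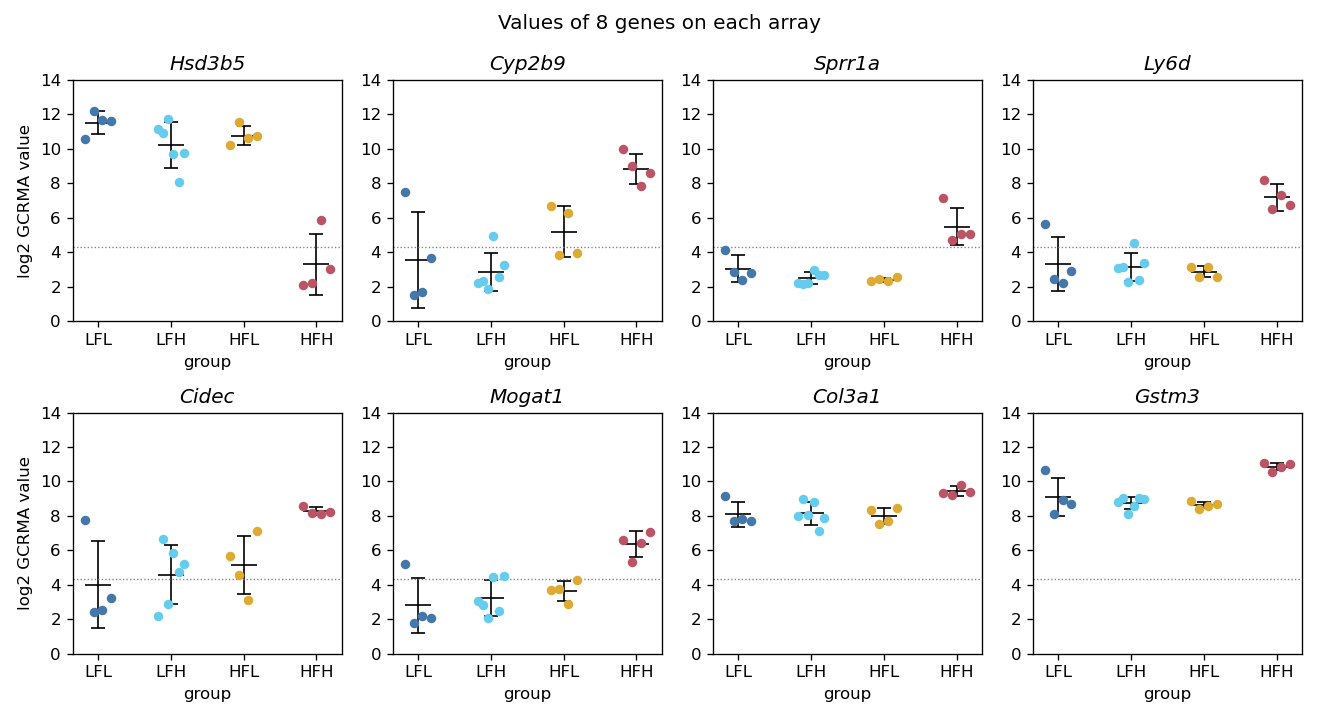
Log2 expression of Hsd3b5, Cyp2b9, Sprr1a, Ly6d, Cidec, Mogat1, Col3a1 and Gstm3 on each of the 18 arrays, by group (LFL n = 4, LFH n = 6, HFL n = 4, HFH n = 4). Points are arrays, the bar is the group mean, the error is the SD and the dotted line is the log2 of 20 (4.32); Hsd3b5 averaged 3.3 in HFH and 10.78 in HFL, while Ly6d averaged 7.19 in HFH and 2.86 in HFL.

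Benign steatosis on the low-fat diet differed from normal liver on that diet in 1 gene. Enho, which encodes the secreted peptide adropin, fell from 5.03 ± 0.57 (SD, n = 4) in LFL to 2.95 ± 0.61 (n = 6) in LFH, at least 1.64-fold (fitted log2 fold change -2.08, SE 0.31, adjusted p = 0.0216). The collagen, keratin and macrophage genes of the histology panel did not pass, with Col3a1 at 0.05 (SE 0.33, adjusted p = 0.98), Krt8 at 0.21 (SE 0.13, adjusted p = 0.615), Krt18 at 0 (SE 0.09, adjusted p = 0.996), Adgre1 at 0.13 (SE 0.19, adjusted p = 0.872) and Cd68 at 0.03 (SE 0.25, adjusted p = 0.982). Cd36 (0.91, SE 0.34, adjusted p = 0.386) and Pparg (0.93, SE 0.35, adjusted p = 0.382) did not pass. The comparison asked what accompanies fat accumulation in the absence of a high-fat diet.

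The list with the smallest camera p in LFH against LFL was that for the unfolded protein response, whose chaperones and enzymes fold proteins in the endoplasmic reticulum. Of its 20 members 0 passed over all genes and 15 were down adjusted over the list alone. The median log2 fold change was -0.37 (camera adjusted p = 1.35e-13, adjusted p = 0.16 with an estimated correlation). With the clock score as a covariate 3 of the 7 called lists stayed called. None of the 6 called lists other than the unfolded protein list had a member passing over all genes. De novo lipogenesis had a median of 0.25 over 23 genes, with 0 adjusted over the list alone (adjusted p = 4.95e-05, and adjusted p = 0.709 with an estimated correlation). Fatty acid oxidation had a median of 0.13 over 29 genes, with 0 adjusted over the list alone (adjusted p = 0.000945, and adjusted p = 0.755 with an estimated correlation). Lipid droplet genes had a median of 0.29 over 22 genes, with 0 adjusted over the list alone (adjusted p = 0.00296, and adjusted p = 0.755 with an estimated correlation). Male-biased genes had a median of -0.27 with 3 of 24 down adjusted over the list alone (adjusted p = 0.000177, and adjusted p = 0.709 with an estimated correlation). Female-biased genes had a median of 0.41 with 5 of 13 up and 1 down adjusted over the list alone (adjusted p = 0.000648, and adjusted p = 0.488 with an estimated correlation). The glucose and insulin list had a median of 0.09 over 19 genes, with 0 adjusted over the list alone (adjusted p = 0.0363, and adjusted p = 0.488 with an estimated correlation).

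After Enho the smallest p-values in LFH against LFL belonged to Serp1, a stress-associated protein of the endoplasmic reticulum (-0.35, adjusted p = 0.228), the glycogen branching enzyme Gbe1 (0.31), the mannose-activating enzyme Gmppb (-0.98) and the methyltransferase Inmt (0.32), the latter 3 all at an adjusted p = 0.231. At an unadjusted p under 0.05 there were 775 genes, where 382 would be expected if no gene differed. Genes are correlated, so such a count can lie well away from 382 without any difference. Without LFL replicate 1, the array with high Cidec, 68 genes passed, while the count was 0 without LFL replicate 2, LFL replicate 3 or LFH replicate 4 and 2 without LFH replicate 1, 2 or 6. Enho lost the call in 4 of 10 cases, with values between -2.24 and -1.81 (the latter without LFL replicate 4), and LFH replicate 2, the array with adipose markers, belongs to this comparison. The adipocyte list had a median of 0.37 with 6 of 6 genes above 0 (adjusted p = 0.0807, not called). Without LFH replicate 2 the called lists went from 7 to 5 and the upward ones from 5 to 3, and the same numbers were found without LFL replicate 2.

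Pre-NASH on the high-fat diet and normal liver on the low-fat diet, both from low responders, did not differ at any gene past the adjusted threshold. Socs3, a feedback inhibitor of cytokine signalling, came closest together with the carboxylesterase Ces2e. Socs3 was 6.73 ± 0.83 (SD, n = 4) in LFL and 4.89 ± 0.32 (n = 4) in HFL (log2 fold change -1.84, SE 0.3, adjusted p = 0.0541), and Ces2e differed by 0.5 (SE 0.08, adjusted p = 0.0541). Enho (at least 1.64-fold lower), Gadd45g, a growth arrest gene (-2.87), and Nkrf (0.57) followed, each at an adjusted p = 0.26. For these 5 genes the HFL and LFL arrays did not overlap. They were picked by smallest p from the same arrays, so this adds no support for them. The comparison set the 2 diets side by side in animals without overt disease. These animals were picked by histology after the diet, so it does not isolate the effect of the diet.

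Genes of fatty acid oxidation, many of them targets of the receptor PPARA, leaned upward in HFL against LFL, with a median log2 fold change of 0.25 over 29 genes (0 adjusted over the list alone, camera adjusted p = 4.86e-09, adjusted p = 0.333 with an estimated correlation). Lipid droplet genes had a median of 0.25 over 22 genes (1 up adjusted over the list alone, adjusted p = 0.00102, and adjusted p = 0.468 with an estimated correlation). The unfolded protein list had a median of -0.24, with all 20 members below 0 (0 adjusted over the list alone, adjusted p = 2.81e-07, and adjusted p = 0.333 with an estimated correlation). Acute phase and complement genes had a median of -0.15 over 26 genes (2 down adjusted over the list alone, adjusted p = 2.72e-05, and adjusted p = 0.333 with an estimated correlation). Hepatocyte secretory genes had a median of -0.07 over 20 genes (1 down adjusted over the list alone, adjusted p = 8.48e-05, and adjusted p = 0.0973 with an estimated correlation). Male-biased genes had a median of -0.27 (0 of 24 adjusted over the list alone, adjusted p = 0.000243, and adjusted p = 0.398 with an estimated correlation). Female-biased genes had a median of 0.56 (0 of 13 adjusted over the list alone, adjusted p = 0.00183, and adjusted p = 0.333 with an estimated correlation). Macrophage genes had a median of -0.11 (1 of 26 down adjusted over the list alone, adjusted p = 0.00198, and adjusted p = 0.485 with an estimated correlation), extracellular matrix genes -0.1 (0 of 21 adjusted over the list alone, adjusted p = 0.0149, and adjusted p = 0.494 with an estimated correlation). Stellate cell genes had a median of -0.2 (0 of 15 adjusted over the list alone, adjusted p = 0.0158, and adjusted p = 0.333 with an estimated correlation). Cytochrome P450 and drug metabolism genes had a median of 0.1 with 0 of 23 adjusted over the list alone (adjusted p = 0.00989 and adjusted p = 0.333 with an estimated correlation). Bile acid genes had a median of 0.1 with 0 of 25 adjusted over the list alone (adjusted p = 0.0169 and adjusted p = 0.338 with an estimated correlation). Immediate early genes had a median of -0.07 with 1 of 11 down adjusted over the list alone (adjusted p = 0.0499 and adjusted p = 0.333 with an estimated correlation).

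The limma count for HFL against LFL was 0 of 7634 genes. At an unadjusted p under 0.05 there were 642, where 382 would be expected if no gene differed. The limma count was 2 with array quality weights, 2 with either other scaling, and 30 without LFL replicate 1. Without LFL replicate 2, 3 or 4 it was 1, and the number of called lists went from 13 to 7 without HFL replicate 2.

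Among high responders, 7 of 24 male-biased genes were lower in overt NASH than in benign steatosis, while 5 of 13 female-biased, 5 of 10 injury and 6 of 22 NRF2 and glutathione genes were higher and 2 female-biased genes lower. With an estimated correlation the injury list held its call (adjusted p = 0.048), and the male-biased (adjusted p = 0.0585), female-biased (adjusted p = 0.283) and glutathione (adjusted p = 0.0585) lists did not. Hsd3b5 was 10.22 ± 1.31 (SD, n = 6) in LFH and fell by 6.92 in HFH (SE 0.69, adjusted p = 6.71e-05). Cyp2b9, a cytochrome P450 typical of female mouse liver, rose from 2.86 ± 1.11 (n = 6) to 8.85 ± 0.88 (n = 4), a log2 fold change of 5.99 (SE 0.95, adjusted p = 0.00323). Ly6d rose by 4.05 (adjusted p = 0.00108), Mogat1 by 3.14 (adjusted p = 0.0114), Rad51b, a recombination protein, by 3.2 (adjusted p = 0.0143), and Sprr1a was at least 2.26-fold higher (adjusted p = 0.000796). Further falls were Serpina4-ps1 (-4.14, adjusted p = 0.00598), Slco1a1 (-2.29, adjusted p = 0.00209), Slc22a7 (-1.96, adjusted p = 0.0143) and the vasopressin receptor Avpr1a (-1.82, adjusted p = 0.0486).

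Male-biased genes fell in HFH against LFH for 7 of 24 members and for 16 adjusted over the list alone. The median log2 fold change was -0.63 (camera adjusted p = 4.66e-15, adjusted p = 0.0585 with an estimated correlation). Of 13 female-biased genes 5 rose, among them Slc22a27 (1.93) and Hao2 (1.82), and 2 fell, Lifr (-1.29) and the hepcidin gene Hamp2 (-0.81), both named after their values were seen, with 6 up and 2 down adjusted over the list alone. The median was 0.49 (adjusted p = 0.00408, and adjusted p = 0.283 with an estimated correlation). The injury list held with an estimated correlation (adjusted p = 0.048 there and 7.06e-09 preset, median 0.7), with 5 of 10 genes up and 7 adjusted over the list alone. Among the 5 were Ly6d (4.05, adjusted p = 0.00108), Anxa2 (1.74, adjusted p = 0.00891) and Krt8 (0.64, adjusted p = 0.0124). The hepatocyte secretory list also held (adjusted p = 0.0177 with an estimated correlation and 2.83e-07 preset, median -0.09), with 6 of 20 genes down and 8 adjusted over the list alone, including Foxa3 (-1.07), plasminogen (Plg, -0.21) and fetuin (Ahsg, -0.24). NRF2 and glutathione genes rose for 6 of 22 members, with 16 up and 1 down adjusted over the list alone. The median was 0.36 (adjusted p = 5.48e-10, and adjusted p = 0.0585 with an estimated correlation). Extracellular matrix genes rose for 4 of 21, including Col3a1 (1.29) and Postn (0.78), and fell for 1, Fn1 (-0.34, named after its values were seen), with 13 up and 1 down adjusted over the list alone. The median was 0.52 (adjusted p = 2.83e-07, and adjusted p = 0.199 with an estimated correlation).

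In the same contrast lipid droplet genes rose for 2 of 22, Mogat1 and the lipoprotein receptor gene Vldlr (1.33), and for 7 adjusted over the list alone. The median was 0.39 (adjusted p = 9.8e-07, and adjusted p = 0.246 with an estimated correlation). Cholesterol synthesis genes rose for 1 of 21, Hmgcs1 (0.63), and for 9 adjusted over the list alone. The median was 0.46 (adjusted p = 3.59e-07, and adjusted p = 0.283 with an estimated correlation). Fatty acid oxidation genes rose for 0 of 29 and 6 adjusted over the list alone. The median was 0.2 (adjusted p = 4.57e-05, and adjusted p = 0.334 with an estimated correlation). Macrophage genes rose for 1 of 26, Mmp12 (2.18), and for 3 adjusted over the list alone. The median was 0.27 (adjusted p = 3.22e-05, and adjusted p = 0.334 with an estimated correlation). Bile acid genes fell for 6 of 25 and rose for 1, with 7 down and 2 up adjusted over the list alone. The median was -0.1 (adjusted p = 0.00318, and adjusted p = 0.232 with an estimated correlation). The rise was that of the phospholipid transporter gene Abcb4 (0.39), named after its values were seen, while the bile acid uptake transporter Slc10a1 fell by 0.33 and the conjugating ligase Slc27a5 by 0.18. Immediate early genes rose for 3 of 11 and 3 adjusted over the list alone. The median was 0.22 (adjusted p = 0.0059, and adjusted p = 0.178 with an estimated correlation). Cell cycle genes rose for 1 of 5, the helicase subunit gene Mcm6 (0.9), and 4 adjusted over the list alone. The median was 0.57 (adjusted p = 0.00076, and adjusted p = 0.178 with an estimated correlation). Pericentral genes rose for 1 of 14, Slc13a3 (0.94), with 6 up and 1 down adjusted over the list alone. The median was 0.07 (adjusted p = 0.0257, and adjusted p = 0.334 with an estimated correlation).

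The HFH and LFH arrays overlapped for the called genes Abcg5, Cps1, Hao2, Mmp12, Slc22a27 and Vldlr and for no other called gene named by the rule. Other probe sets did not pass for Slc13a3 (1 of 1), Slc10a1 (1 of 1), Avpr1a (1 of 1) and Serpina4-ps1 (2 of 2). Avpr1a also lost its call in 6 of 10 cases with 1 array left out. HFH and LFH differed at 183 genes, 42 of them by more than 2-fold, with 81 higher and 102 lower in HFH (96 and 86 with only the 2 groups in the fit). The count was 48 without HFH replicate 1, 85 without HFH replicate 4, 91 without LFH replicate 3, 95 without HFH replicate 2 and 103 without HFH replicate 3, and 18 of the 39 named genes called were called whichever array was left out, Col3a1 (lost in 8 of 10 cases) not among them.

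Overt NASH was also compared with normal liver, a contrast of both diet and responder class. Hsd3b5 fell by 8.23 from 11.53 ± 0.67 (SD, n = 4) in LFL (SE 0.75, adjusted p = 1.89e-05). In the male-biased list 17 of 24 genes fell while 1 rose. Cyp2b9 rose by 5.27 (SE 1.04, adjusted p = 0.00567), and 8 of 13 female-biased genes rose while 1 fell. Cidec rose from 3.99 ± 2.53 (n = 4) to 8.27 ± 0.23 (n = 4), a log2 fold change of 4.28 (SE 1.1, adjusted p = 0.019), with Mogat1 at 3.56 (adjusted p = 0.00416), Pparg, the nuclear receptor of fat storage, at 1.83 (adjusted p = 0.00753), Cd36 at 1.91 (adjusted p = 0.0057) and Plin2 at 0.45 (adjusted p = 0.0149). Ly6d rose by 3.88 (adjusted p = 0.00144), Osbpl3, an oxysterol-binding protein, by 3.58 (adjusted p = 0.0108), Krt8 by 0.85 (adjusted p = 0.00201) and Col3a1 by 1.34 (adjusted p = 0.0245), while Serpina4-ps1 (-6.52), Avpr1a (-2.97), Slc22a7 (-2.67) and Ugt2b38 (at least 4.42-fold) were the other largest falls.

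By list, male-biased genes had 20 down and 1 up adjusted over the list alone in HFH against LFL. The median log2 fold change was -0.84 (camera adjusted p = 6.14e-14, adjusted p = 0.148 with an estimated correlation). Female-biased genes had 10 up and 1 down adjusted over the list alone. The median was 1.49 (adjusted p = 2.45e-05, and adjusted p = 0.203 with an estimated correlation). Fatty acid oxidation genes rose for 11 of 29, including Vnn1 (1.4), Pex11a (0.94) and Aldh3a2 (0.87), and for 15 adjusted over the list alone. The median was 0.36 (adjusted p = 1.91e-06, and adjusted p = 0.355 with an estimated correlation). Lipid droplet genes rose for 9 of 22 and 13 adjusted over the list alone. The median was 0.48 (adjusted p = 2.64e-07, and adjusted p = 0.27 with an estimated correlation). NRF2 and glutathione genes rose for 10 of 22 and fell for 1, with 12 and 1 adjusted over the list alone (median 0.45, adjusted p = 1.95e-06, and adjusted p = 0.203 with an estimated correlation), for example Srxn1 (1.27) and the efflux pump gene Abcc3 (0.76). Unfolded protein genes fell for 6 of 20, including Sdf2l1 (-1.61), Creld2 (-1.03) and Atf4 (-0.65), and rose for 1, with 12 and 1 adjusted over the list alone. The median was -0.36 (adjusted p = 8.56e-06, and adjusted p = 0.276 with an estimated correlation). Injury genes rose for 6 of 10, with 6 up and 1 down adjusted over the list alone. The median was 0.67 (adjusted p = 0.000144, and adjusted p = 0.203 with an estimated correlation). Hepatocyte secretory genes fell for 8 of 20 and 9 adjusted over the list alone, and held with an estimated correlation (adjusted p = 0.0388 there and 4.08e-06 preset, median -0.14), with Foxa3 at -1.28 and Fetub at -0.51.

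In the same contrast extracellular matrix genes rose for 5 of 21 and fell for 2, with 14 and 2 adjusted over the list alone. The median was 0.46 (adjusted p = 0.000151, and adjusted p = 0.355 with an estimated correlation). Macrophage genes rose for 2 of 26, Mmp12 (2.32) and the phagocyte receptor gene Clec7a (1.48), and for 1 adjusted over the list alone. The median was 0.31 (adjusted p = 0.000597, and adjusted p = 0.493 with an estimated correlation). Cholesterol synthesis genes rose for 3 of 21, Hmgcs1, Msmo1 and Hsd17b7, and for 8 adjusted over the list alone. The median was 0.45 (adjusted p = 0.000135, and adjusted p = 0.469 with an estimated correlation). De novo lipogenesis genes rose for 4 of 23 and fell for 1, with 7 and 1 adjusted over the list alone. The median was 0.4 (adjusted p = 0.00192, and adjusted p = 0.616 with an estimated correlation). The fatty acid elongase gene Elovl5 rose by 0.47 (adjusted p = 0.00434), whereas Fasn (0.27, adjusted p = 0.668) and Scd1 (0.11, adjusted p = 0.22) did not pass. Cell cycle genes rose for 1 of 5 and 2 adjusted over the list alone. The median was 0.51 (adjusted p = 0.0245, and adjusted p = 0.355 with an estimated correlation). The adipocyte list rose for 2 of 6, Cidec and the carbonic anhydrase gene Car3 (0.16), both also expressed in liver, and for 3 adjusted over the list alone. The median was 0.69 (adjusted p = 0.017, and adjusted p = 0.355 with an estimated correlation).

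Members that moved against their list were named after their values were seen. They were Trim24 (1.09) of the male-biased list, Lifr (-1.92) of the female-biased list, Gstp1 (-0.35, glutathione) and Trib3 (0.9, unfolded protein). Fn1 (-0.33) and Mmp14 (-0.38) of the matrix list and Mlxipl (-0.68, lipogenesis) were the others. No female livers were measured, so the sex bias of list members, Trim24 among them, was not checked here. The HFH and LFL arrays overlapped for the called genes Anxa2, Clec7a, Creld2, Gstm3, Hsd17b7, Krt18, Mmp12, Nid1, Pex11a, Sdf2l1, Tkt and Vldlr. Among the genes given here, other probe sets did not pass for Atf4 (1 of 1), Hsd17b7 (2 of 2) and Car3 (3 of 3). HFH and LFL differed at 941 genes, 501 higher and 440 lower in HFH, 128 of them by more than 2-fold, and 32 of the 53 named genes called were called whichever array was left out, Cidec (lost in 4 of 8 cases) not among them. The count was 1485 without LFL replicate 1, 564 without LFL replicate 3, 478 without HFH replicate 4, 449 without HFH replicate 1, 337 without LFL replicate 4, 297 without LFL replicate 2 and 53 with the clock score as a covariate.

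Whether the gap between high and low responders depended on diet was tested by the interaction, in which 10 genes differed, 4 with a positive and 6 with a negative interaction. Hsd3b5 had an interaction of -6.17 (SE 1.02, adjusted p = 0.0342) and Sprr1a an interaction of 3.64 (SE 0.57, adjusted p = 0.0342). Inmt, which was higher in LFH (12.14 ± 0.13, SD, n = 6) than in LFL (11.81 ± 0.08, n = 4) and lower in HFH (11.77 ± 0.1, n = 4) than in HFL (12.05 ± 0.11, n = 4), had an interaction of -0.6 (SE 0.1, adjusted p = 0.0342). Ly6d (4.5), Gstm3 (2.57), Cyp2c54 (-1.82), the chondromodulin gene Cnmd (-1.37), the sterol transporter gene Abcg5 (-0.9) and Arl2bp (0.87) each reached an adjusted p = 0.0489, as did the methionine cycle enzyme Ahcy (-0.3), named after its values were seen.

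Of 30 lists 17 were called in the interaction, 12 up and 5 down. The injury list (median 0.63, preset adjusted p = 1.87e-09, adjusted p = 0.0411 with an estimated correlation) had 1 of 10 members passing, Ly6d, and 8 adjusted over the list alone. Immediate early genes (median 0.47, preset adjusted p = 2.24e-05, adjusted p = 0.0411 with an estimated correlation) had 0 of 11 passing and 4 adjusted over the list alone. Extracellular matrix had a median of 0.52 with 0 of 21 passing, 8 up and 1 down adjusted over the list alone (adjusted p = 1.66e-10 and adjusted p = 0.0956 with an estimated correlation). Macrophage genes had a median of 0.4 with 0 of 26 passing, 2 adjusted over the list alone (adjusted p = 1.55e-09 and adjusted p = 0.136 with an estimated correlation). NRF2 and glutathione genes had a median of 0.2 with 1 of 22 passing, 5 adjusted over the list alone (adjusted p = 1.04e-06 and adjusted p = 0.122 with an estimated correlation). Cholesterol synthesis had a median of 0.33 with 0 of 21 passing, 0 adjusted over the list alone (adjusted p = 2.46e-05 and adjusted p = 0.279 with an estimated correlation). Unfolded protein genes had a median of 0.22 with 0 of 20 passing, 0 adjusted over the list alone (adjusted p = 5.57e-05 and adjusted p = 0.217 with an estimated correlation). Cell cycle had a median of 0.59 with 0 of 5 passing, 2 adjusted over the list alone (adjusted p = 0.000369 and adjusted p = 0.126 with an estimated correlation). Acute phase and complement had a median of 0.1 with 0 of 26 passing, 1 adjusted over the list alone (adjusted p = 0.00338 and adjusted p = 0.279 with an estimated correlation). Cytokines and chemokines had a median of 0.28 with 0 of 14 passing, 2 up and 1 down adjusted over the list alone (adjusted p = 0.00831 and adjusted p = 0.23 with an estimated correlation). Sinusoidal endothelium had a median of 0.11 with 0 of 18 passing, 0 adjusted over the list alone (adjusted p = 0.00831 and adjusted p = 0.136 with an estimated correlation). Stellate cell genes had a median of 0.26 with 0 of 15 passing, 0 adjusted over the list alone (adjusted p = 0.0191 and adjusted p = 0.226 with an estimated correlation).

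There were 5 downward calls in the interaction. Male-biased genes had a median of -0.28 with 1 of 24 passing, 5 adjusted over the list alone (adjusted p = 2.05e-06 and adjusted p = 0.191 with an estimated correlation). Bile acid genes had a median of -0.16 with 1 of 25 passing, 4 adjusted over the list alone (adjusted p = 2.51e-06 and adjusted p = 0.072 with an estimated correlation). Cytochrome P450 and drug metabolism had a median of -0.17 with 1 of 23 passing, 6 down and 1 up adjusted over the list alone (adjusted p = 5.35e-05 and adjusted p = 0.0956 with an estimated correlation). Glucose and insulin genes had a median of -0.17 with 0 of 19 passing, 0 adjusted over the list alone (adjusted p = 0.0118 and adjusted p = 0.136 with an estimated correlation). Periportal genes had a median of -0.25 with 0 of 12 passing, 1 adjusted over the list alone (adjusted p = 0.0118 and adjusted p = 0.141 with an estimated correlation). Against 631 genes at an unadjusted p under 0.05, the limma count was 0 without LFH replicate 6 and without each of HFL replicates 1, 2, 3 and 4. It was 1 without LFH replicate 1 or HFH replicate 1, 2 without LFH replicate 5 or HFH replicate 2, 3 without LFH replicate 3 or 4, 4 without LFL replicate 1 or HFH replicate 3, 5 without LFL replicate 3 or LFH replicate 2, 6 without HFH replicate 4, and 21 without LFL replicate 2. None of the 9 named genes was called whichever array was left out. The 1 other probe set of Gstm3 did not pass.

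**Figure D2:**
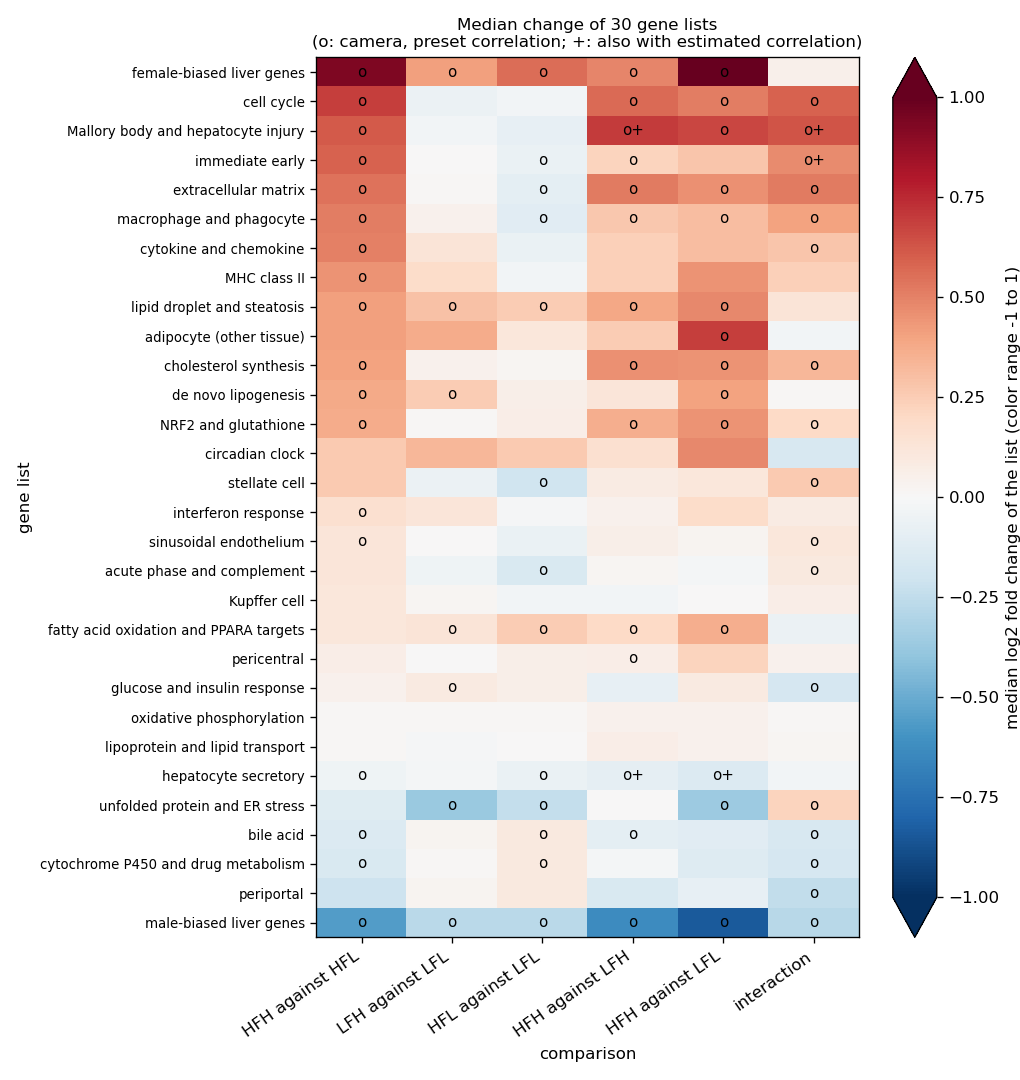
Median log2 fold change of the tested members of 30 gene lists, listed down the side, in the 6 contrasts, listed along the axis, on a colour scale centred at 0. A circle marks a camera call at the preset correlation and a plus a call that also held with an estimated correlation; male-biased genes ranged from -0.84 in HFH against LFL to -0.27 in HFL against LFL.

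Across genes, the changes between high and low responders were compared between the diets. The log2 fold changes of HFH against HFL and of LFH against LFL, which share no array, correlated at r = 0.4 (Spearman's rho 0.39, jackknife SE over arrays 0.26) with 64.1% of 7634 genes of the same sign, and 150 of the 192 genes called in the former had the same sign in the latter. No gene was called in both, and 5 of 100 splits of the arrays within each diet, the real split included, gave as high a correlation. The diet changes of low and high responders correlated at r = 0.32 (rho 0.26, jackknife SE 0.28), with 59.7% of genes of the same sign. Genes are not independent replicates, so no p is given. The correlations ranged from 0.24 to 0.54 and from 0.15 to 0.49 when arrays were left out, both lowest without LFL replicate 2 (0.24 and 0.15) and highest without LFL replicate 1.

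In all 6 contrasts the lists for lipoprotein and lipid transport, Kupffer cells, the circadian clock and oxidative phosphorylation were not called by camera, which tests for a shift in a single direction. For HFH against HFL their medians were 0.01 (adjusted p = 0.787), 0.11 (adjusted p = 0.667), 0.26 (adjusted p = 0.748) and 0.01 (adjusted p = 0.136). Single members passed nonetheless. In the lipoprotein list, of 18 genes, 0 rose and 2 fell in HFH against HFL, 1 rose and 1 fell in HFH against LFH, and 3 rose and 4 fell in HFH against LFL. The fry test for change in either direction gave this list an adjusted p of 5.55e-06, 2e-05 and 8.98e-07 in these contrasts. In HFH against LFL 2 of 15 clock genes fell (adjusted p = 0.0296 by that test), as did 2 of 15 Kupffer cell genes (adjusted p = 0.101), and 1 of 36 oxidative phosphorylation genes rose (adjusted p = 0.0832). For every called list the median, the mean and the test had the same sign.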

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

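Tests chosen only after the result was seen were the comparison of male-biased with hepatocyte secretory genes, the clock tests of male-biased and female-biased genes (the clock score was chosen after the data were seen), and the tests on LFL replicate 1 and LFH replicate 2.

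Among 289 combinations of a named gene and a group, 14 had an array far from the others of its group, where 14.4 would be expected at 1 in 20. Of these, 6 lay on LFL replicate 1. They were Cidec at 7.74 (nearest other LFL array 3.25), Mogat1 at 5.19 (2.21), Osbpl3 at 5.72 (2.38), Col3a1 at 9.18 (7.8), C8b at 9.76 and Fmo1 at 9.94. On HFH replicate 1 they were Sprr1a at 7.13, Cyp2c50 at 11.64 and Plin3 at 8.14. Single arrays were Adh6-ps1 at 5.38 on HFL replicate 2, Ahsg at 13.02 on LFH replicate 3, Cnmd at 5.35 on HFH replicate 3, Cps1 at 12.3 on HFH replicate 4 and Plg at 12.94 on LFL replicate 3.

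The gap between high and low responders differed between diets, by the interaction test, for Hsd3b5 (-6.17), Ly6d (4.5), Sprr1a (3.64), Gstm3 (2.57), Cyp2c54 (-1.82), Cnmd (-1.37), Abcg5 (-0.9), Arl2bp (0.87), Inmt (-0.6) and Ahcy (-0.3). Of the 17 lists called in the interaction only Mallory body and hepatocyte injury and immediate early (adjusted p = 0.0411 for both) held with an estimated correlation, and the other 15 did not. By list, medians of the interaction were 0.63 for Mallory body and hepatocyte injury, 0.59 for cell cycle, 0.52 for extracellular matrix, 0.47 for immediate early, 0.4 for macrophage and phagocyte, 0.33 for cholesterol synthesis, 0.28 for cytokine and chemokine, 0.26 for stellate cell, 0.22 for unfolded protein, 0.2 for NRF2 and glutathione, 0.11 for sinusoidal endothelium and 0.1 for acute phase and complement. They were -0.28 for male-biased genes, -0.25 for periportal, -0.17 for cytochrome P450 and drug metabolism, -0.17 for glucose and insulin response and -0.16 for bile acid.

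Only the real split of the arrays called as many genes in HFH against HFL (192, 1 of 35 splits, highest other 0), HFH against LFH (183, 1 of 100, highest other 2) and HFH against LFL (941, 1 of 35, highest other 0). This argues against no difference at all there and does not bear on the size of the counts. With 4 arrays in each group there were only 35 splits, so no share could be smaller than 1 of 35. For the interaction (10 genes, 1 of 100, highest other 1) the splits mixed the arrays of all 4 groups. That also breaks up the differences between HFH and the other groups, so these splits do not decide on chance for the interaction. Chance was not excluded for LFH against LFL (1 gene, 14 of 100, highest other 295). For HFL against LFL (0 genes by limma, 642 at an unadjusted p under 0.05, highest other 80) no split can call fewer, so the count of 35 of 35 splits says nothing on chance. The split with 295 genes set LFL replicate 1 with LFH replicates 2 to 6, and the split with 80 set it with HFL replicates 1, 2 and 4, which points to a structure of the samples around this array. For the number of called lists in the interaction (17 lists, 2 of 100, highest other 17) the splits do not decide on chance, for the same reason. Chance was not excluded for the called lists in HFH against HFL (18, 4 of 35, highest other 22), LFH against LFL (7, 66 of 100, highest other 19), HFL against LFL (13, 7 of 35, highest other 17), HFH against LFH (14, 9 of 100, highest other 18) or HFH against LFL (14, 10 of 35, highest other 18). Nor was it excluded for the correlation of high-against-low responder changes between diets (0.4, 5 of 100, highest other 0.64).

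In HFH against HFL 11 of 24 male-biased genes were lower (list median -0.56) and 1 of 13 female-biased genes was higher and 1 lower (list median 0.93), and neither list kept its call with an estimated correlation (adjusted p = 0.104 and 0.167). Against female livers among the HFH arrays, 3 Y-linked genes averaged -0.08 relative to the other arrays and Xist read at most 1.9 on any array. On a lower share of hepatocytes, the male-biased median lay 0.52 below that of hepatocyte secretory genes (-0.52, interval -1.03 to -0.2). The interval came from resampling genes, which are not independent replicates, and holds no spread between animals. It therefore does not decide on the share of hepatocytes. Against a difference in clock phase as the whole cause, the male-biased median was -0.51 with the clock score as a covariate (camera adjusted p = 4.97e-11 at the preset correlation) and Hsd3b5 was at -6.9, although the number of changed genes went from 192 to 48. For female-biased genes the median went from 0.93 to 0.45 (camera adjusted p = 0.0072 at the preset correlation) with that score, so clock phase and disease cannot be told apart there. For both lists the adjustment is limited, because the score itself differed between groups. Of the HFL arrays only replicate 4 (0.7) had a score within the HFH range of 0.52 to 0.82. A biological difference between the disease classes remains a hypothesis for the male-biased genes.

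LFL replicate 1 stood apart from the other LFL arrays, with a mean correlation of 0.9885 with HFH (best partner HFH replicate 3), 0.9883 with HFL, 0.9856 with LFH and 0.9823 with LFL arrays, and a lipid droplet mean of 8.78 against 7.33, 7.58 and 7.65. With its label and that of LFH replicate 1 exchanged, 295 genes differed between LFH and LFL, the most of 24 such exchanges, although LFH replicate 1 ranked 4 among the LFH arrays by correlation with LFL replicates 2 to 4 and its lipid droplet mean was 7.79. An exchange with LFH replicate 3 gave 133 genes, and that array had the highest such correlation of the LFH arrays (0.9843) and a lipid droplet mean of 7.56. An exchange with LFH replicate 1 and an animal unlike its group cannot be told apart, since no measure independent of expression was at hand, and an exchange with LFH replicate 3 stays open too. The exchanges run as such were between LFL and LFH arrays alone. HFL replicates 2 and 3 correlated with LFL replicates 2 to 4 at 0.9858 and 0.9856, above any LFH array, with lipid droplet means of 8.19 and 7.75. The split with 80 genes in HFL against LFL amounts to an exchange with HFL replicate 3. An exchange with an HFL array therefore stays open as well. Against adipose tissue RNA, Adipoq on this array lay 1.22 below the highest of the other LFL arrays (-1.22).

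LFH replicate 2 had the highest value of all 18 arrays for 7 of 11 adipocyte genes, where 0.61 would be expected with all arrays alike. Adipoq was 8.9, Fabp4 11.99, Retn 4.42, Lipe 5.27 and Pnpla2 8.07 on that array. Lipid storage by hepatocytes was argued against by Adipoq of at most 1.57 on arrays with more Cidec than this array. Adipose tissue RNA in the sample is a candidate explanation, found and tested on the same data. Liver also expresses some of these genes, among them Cidec and Car3.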

How the results depend on the processing

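Leaving out both arrays that stood apart, the clock score and the other reading of the filter were chosen after the data were seen. Signal near background limits genes whose group mean lay below 4.32, whose folds depend on the background correction. The cause was not tested where none is given.

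The number of changed genes in HFH against HFL (192) was 825 with array quality weights, 546 with only the 2 groups in the fit, 44 over 2-fold, 322 without both arrays that stood apart and 48 with the clock score, and 31 to 183 when single arrays were left out. The excess of lower genes there (80 higher, 112 lower) shrank with centred arrays (90 and 91) and quantile normalization (105 and 113), and turned with no filter (71 and 59), array quality weights (419 and 406), only the 2 groups in the fit (313 and 233), over 2-fold (25 and 19) and without both apart arrays (167 and 155). In LFH against LFL (1) it was 0 under the stricter filter (which its only called gene, Enho, did not pass), quantile normalization, only the 2 groups in the fit and the clock score, 2 with the replicate block, 80 without both apart arrays, and 0 to 68 with single arrays left out. In HFL against LFL (0 by limma, 642 at an unadjusted p under 0.05) it was 2 with centred arrays, quantile normalization or array quality weights, 42 without both apart arrays, and 0 to 30 with single arrays left out. In HFH against LFH (183) it was 298 with array quality weights, 42 over 2-fold, 280 without both apart arrays, 154 with the clock score and 48 to 224 with single arrays left out. The excess of lower genes there (81 higher, 102 lower) stayed with centred arrays (77 and 97) and quantile normalization (99 and 109). It was gone with no filter (78 and 78). It turned with only the 2 groups in the fit (96 and 86), over 2-fold (26 and 16), without both apart arrays (152 and 128) and without LFH replicate 4 (107 and 97). In HFH against LFL (941) it was 1651 with array quality weights, 128 over 2-fold, 1545 without both apart arrays, 53 with the clock score and 297 to 1485 with single arrays left out. In the interaction (10) it was 3 with no filter, 0 with all probe sets, 3 with centred arrays, 0 without trend, 18 with array quality weights, 2 with robust eBayes, 3 with the replicate block, 6 over 2-fold, 5 without both apart arrays, 24 with the clock score and 0 to 21 with single arrays left out.

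With an estimated correlation the called lists numbered 0 in HFH against HFL, LFH against LFL and HFL against LFL, 2 in HFH against LFH, 1 in HFH against LFL and 2 in the interaction. With fry they numbered 13 in HFH against HFL, 1 in LFH against LFL, 1 in HFL against LFL, 9 in HFH against LFH, 12 in HFH against LFL and 5 in the interaction, and with the clock score 3 in LFH against LFL. With single arrays left out they ranged from 16 to 21 in HFH against HFL, 5 to 9 in LFH against LFL, 7 to 15 in HFL against LFL, 14 to 18 in HFH against LFH, 13 to 16 in HFH against LFL and 16 to 19 in the interaction. The correlation between the changes on both diets ranged from 0.24 to 0.54 and that of the diet changes from 0.15 to 0.49.

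Replicate numbers were shared between groups, and 9 of 24 same-numbered pairs correlated over 0.1 (mean r 0.02, against -0.01 for other pairs), while 3 of 18 arrays correlated best with their own number, so the numbers do not pair the arrays.

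Signs turned for panel genes that did not pass. With single arrays left out the log2 fold change in HFH against HFL ranged from -0.03 to 0.3 for Adgre1 and -0.05 to 0.42 for Fasn. In LFH against LFL it ranged from -0.41 to 0.1 for Acta2, -0.18 to 0.2 for Cd68, -0.12 to 0.41 for Col3a1, -0.05 to 0.07 for Krt18 and -0.08 to 0.09 for Tgfb1. In HFL against LFL it ranged from -0.03 to 0.19 for Adgre1, -0.26 to 0.12 for Cd68, -0.23 to 0.27 for Col3a1 and -0.15 to 0.32 for Fasn. In HFH against LFH it ranged from -0.11 to 0.24 for Adgre1, -0.22 to 0.22 for Fasn and 0 to 0.06 for Scd1, and in HFH against LFL from -0.14 to 0.43 for Acta2. In the interaction it ranged from -0.16 to 0.19 for Adgre1, -0.33 to 0.51 for Cd36, -0.29 to 0.18 for Fasn and -0.72 to 0.11 for Pparg. Other probe sets gave -0.09 for Cpt1a in HFH against HFL and -0.02 and -0.07 for Cd36 in the interaction, and the replicate block gave 0.03 for Tgfb1 in LFH against LFL and, in the interaction, -0.03 for Adgre1 and 0.02 for Cpt1a. Of all values of named genes with single arrays left out, 1658 kept direction and side of the threshold, 448 no longer passed, 17 newly passed and 55 turned sign.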

Other observations

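Beyond the gene groups described for the contrasts, some lists had too few tested members for a list test. In HFH against HFL single members passed the gene test, and these were chosen after their values were seen. Anxa3, an annexin held in the cholangiocyte list, was at 0.79, Pf4, a platelet chemokine held in the blood cell list, at 0.98, and the elastase gene Cela1, held in the pancreas list, at -1.09. In HFH against LFL the neutrophil list had Lcn2, which encodes lipocalin and is also an acute phase gene, at 2.24. In the same contrast the B and plasma cell list had Ighm, an immunoglobulin heavy chain, at 1.5. The lists for T and NK cells and for muscle had 0 members tested.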
